A study of Mus musculus with 2 samples.

How the data were processed

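Chromatin from the facial prominence of mouse embryos at day 15.5 was immunoprecipitated with an antibody against H3K4me2 and sequenced in 2 libraries, each from its own pool of embryos. Per the labels the pools are biological replicates of 1 group. Per the labels, positions are on mm10. The deposited notes say that each library's list was made from 1 immunoprecipitation alignment and 1 control alignment, that the pooled list was called on both libraries with 2 control alignments, and that the replicated list derives from the other 3. The aligner, the peak caller, its threshold and the rule for a replicated peak are not given in the sources used here. The libraries' reads were not used here.

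Each list gives, per peak, its position, a fold (a ratio) of the pileup at the summit over the expected background, as the authors deposited it. It also gives −log10 of a p-value and of a q-value of the summit, as the authors deposited them, and a display score of the authors scaled within each deposited file. The meaning of the fold was taken from the values: fold and p together were solved for a whole-number pileup and a background, with fold equal to (pileup + 1) / (background + 1) and p equal to a Poisson tail. This gave a solution for 100% of peaks in each list within 0.001 of the deposited −log10 p, and for 0.2001% of simulated pairs whose p had been shuffled. The most frequent background was the same for 43.1% of the peaks of library 1 and 51.8% of library 2, and it served as the measure of relative depth. Median summit pileups were 23 fragments in library 1 and 21 in library 2. The number of fragments at a summit limits the precision of its fold. The score was not used. The lists end at the caller's threshold, so a place without a peak is a place under that threshold in these libraries and not one without the mark.

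Peaks were compared with bedtools 2.31.1, and a peak was shared when the overlap made up at least 50% of either peak. Genes, exons and TSSs came from the basic set of GENCODE M21 on GRCm38 (mm10). Protein-coding genes on chromosomes 1 to 19, X and Y were used, with the outermost annotated TSS as the 5' end. A promoter was CpG-rich when the observed to expected CpG ratio was at least 0.6 and the GC share at least 0.5 over 500 bp on either side. A promoter carried a peak when a replicated peak lay within 1 kb of the 5' end. Covered length was the number of base pairs under replicated peaks within 5 kb of the 5' end. A distal peak lay over 1 kb from every TSS of any gene and was given to the protein-coding gene with the nearest 5' end. Peaks were placed at random on their own chromosome outside assembly gaps, 1000 times for the genomic classes and 100 times for the overlap.

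For each of 23 gene lists, promoters were tested by Fisher's exact test, and covered length (median) and distal peaks (mean) by permutation tests against 100000 random lists of the same size, matched on CpG class for covered length and on decile of territory length for distal peaks, the territory being the stretch nearest to a gene's 5' end. All tests were two-sided with Benjamini-Hochberg adjustment over the lists and a threshold of 0.05. The lists were cranial mesenchyme transcription factors, Dlx, anterior Hox, posterior Hox, facial signalling, osteoblast, chondrocyte, tooth, surface epithelium, suprabasal keratinocyte, skeletal muscle, melanocyte, Schwann cell and glia, sensory and general neuron, endothelium, erythroid, macrophage and leukocyte, hepatocyte, cardiomyocyte, pluripotency and germ line, pancreas and gut, forebrain, and housekeeping. Of their members 301 were matched by symbol, Tf as Trf, and Ahsp was not matched. The genes named were, per list, up to 4 members with the longest covered length and up to 4 without a promoter peak in alphabetical order, the 10 genes with the longest coverage within 10 kb, the 10 with the most distal peaks (ties in alphabetical order), and the genes nearest to the 5 highest and the 5 longest peaks. Lists, tests, named genes and alternatives were chosen before the data were examined, except where another origin is stated. Some members outside the rule are named as examples of a list and were chosen after their values were seen. Values over the 2 libraries are given as mean ± SD. With 2 libraries no test between them was possible.

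The alternatives were another overlap (1 bp, or 50% of both peaks), stricter peaks (−log10 q of at least 2 or 5), equal numbers of peaks, each library's own list (without replicate 1, without replicate 2), the pooled list, promoter windows of 500 bp and 2.5 kb, any TSS of a gene, a CpG ratio of 0.75, CpG-rich promoters only, covered windows of 2 and 20 kb, unmatched random lists, distal peaks over 5 kb from every TSS or within 100 kb of the 5' end, and, chosen after seeing the data, only replicated peaks found in both libraries and CpG-poor promoters only.

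The steps were tested on simulated data. Of 200 random lists of 15 genes, 2% were called for covered length, 4.5% for distal peaks and 2% for promoters at a raw p under 0.05 by permutation or exact test. After the covered length of the members was multiplied by 2, 78.5% of lists were called, and 38.5% for distal peaks multiplied by 2. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, pysam 0.24.0, minimap2 2.31-r1302 and matplotlib 3.10.9.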

Results

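Histone H3 dimethylated at lysine 4 (H3K4me2), a mark of promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in the facial prominence of mouse embryos of the B6NCrl strain at embryonic day 15.5. The facial prominence is the tissue that forms the jaws, palate and nose. The series held 1 group of 2 libraries, each from a separate pool of embryos of mixed sex, 78 embryos for library 1 and 62 for library 2. There was no second tissue, stage or treatment, so the comparisons below were between the libraries, between kinds of region and between lists of genes. The peak list of library 1 held 46277 peaks over 46329994 bp, and that of library 2 held 46604 peaks over 45662484 bp. Total read numbers were not used here. The relative depth was read from the most frequent expected background pileup of a list's peaks, which was 3.00 fragments in library 1 and 2.64 in library 2, a ratio of 1.14. The list called on both libraries together held 51421 peaks at a background of 5.78, and the replicated list derived from these 3 lists held 35549. Positions are given on the mouse build GRCm38 (mm10), counted from 1.

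The peak with the highest fold of the replicated list lay over the 5' end of Egr1, an immediate early transcription factor gene, on chromosome 18 at 34858972 to 34863944, and the libraries listed it at 44.1-fold and 49.8-fold over background. The next peaks covered the 5' ends of Zbtb46 on chromosome 2 (181457893 to 181460670), Rasgef1c on chromosome 11 (49901354 to 49902729), Cabp1 on chromosome 5 (115192326 to 115195199) and Rragd on chromosome 4 (32982464 to 32985577). The libraries listed these at 50.6 and 48.9, 52.0 and 42.6, 46.5 and 46.9, and 47.5 and 45.2, in that order, so that in library 1 Egr1 had the lowest fold of the 5. Fold values per peak are those of the authors. Of the peaks of library 1, 34296 (74.1%, 95% Wilson interval 73.7 to 74.5%) overlapped a peak of library 2 by at least 50% of either peak's length, and of the peaks of library 2, 35181 did (75.5%, 75.1 to 75.9%). These intervals cover counting error only. Random placement of the peaks of library 2 gave a mean of 2.82% of library 1 peaks (SD 0.0771 over 100 placements). The Jaccard index over base pairs was 0.753, and no peak had the same start and end in both libraries. Peaks without a partner were low and short: in library 1 their median fold was 3.07 and their median width 245 bp, against 10.6 and 965 bp for shared peaks, and in library 2 the values were 3.02 and 238 bp against 10.2 and 924 bp. Over 32471 pairs of shared peaks, the folds of the libraries correlated across peaks with Spearman's rho 0.934 and Pearson's r 0.944 (log2). Peaks are not independent replicates, so no p-value was computed.

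The longest replicated peak, 16625 bp on chromosome 11 at 85828946 to 85845570, covered the 5' end of Tbx2, a T-box transcription factor gene, and was 16231.5 ± 249.6 bp long in the separate libraries (SD, n = 2). It was followed by peaks over Ptch1, the Hedgehog receptor gene (15978 bp on chromosome 13 at 63558413 to 63574390), Wnt5a, a Wnt ligand gene (14909 bp on chromosome 14 at 28503922 to 28518830), Tnrc18 (14659 bp on chromosome 5 at 142810522 to 142825180) and Mn1, a gene of craniofacial bone development (14000 bp on chromosome 5 at 111414762 to 111428761). The peak over Ptch1 was called in pieces in the separate libraries, 6 in library 1 and 8 in library 2. So were those over Tnrc18 (2 in library 1 and 4 in library 2), Wnt5a (3 in library 1) and Mn1 (4 in library 2). The replicated list kept 69.1% of the pooled peaks. Kept peaks had a median fold of 9.92 and a median width of 1041 bp, and the 15872 peaks left out had a median fold of 2.63 and a median width of 250 bp, so that the ratio of median folds was 3.78. Of the kept peaks, 32173 overlapped a peak of both libraries by at least 50% of either length, 3194 a peak of 1 library and 182 a peak of neither.

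Promoters were the main site of H3K4me2. Of the 35535 replicated peaks on chromosomes 1 to 19, X and Y, 17915 (50.4%) lay within 1 kb of an annotated transcription start site (TSS), where random placement gave 7.35% (SD 0.139), a 6.85-fold excess. Exons outside these windows held 7.09% of the peaks, introns 20.8% and intergenic sequence 21.7%. These shares were 0.731, 0.627 and 0.436 of those under random placement. All 4 differences had a permutation p of 0.002, the smallest that 1000 placements can give in a two-sided test. The excess near TSSs was 4.42-fold with a window of 2.5 kb and 9.05-fold with 500 bp, and 5.73-fold with the pooled list.

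**Figure D1:**
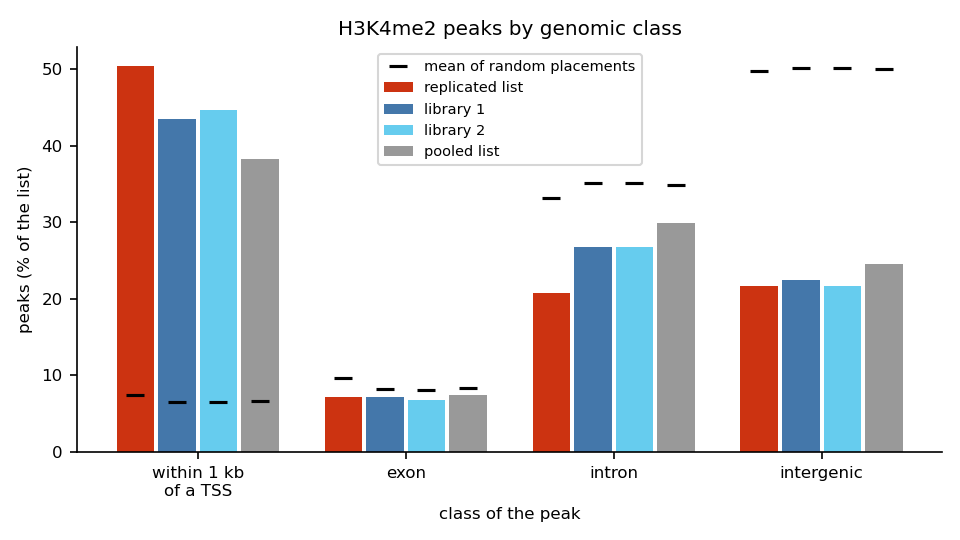
Share of H3K4me2 peaks (y axis, percent of the list) in each genomic class (x axis) for the replicated list, each library's own list and the pooled list, with short black lines for the mean of 1000 random placements. Peaks within 1 kb of a TSS made up 50.4% of the replicated list, 43.6% of library 1, 44.7% of library 2 and 38.2% of the pooled list, against 7.35% at random for the replicated list.

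Peaks at TSSs were also taller and wider than the rest. A peak counted as near a TSS when any part of it lay within 1 kb. Wide peaks enter this class more easily, so part of the difference in width may be built in. In library 1 the median fold was 16.8 for 20158 peaks within 1 kb of a TSS and 3.65 for 26102 distal peaks, and in library 2 it was 15.8 for 20846 and 3.57 for 25739. The ratio of median folds was 4.52 ± 0.132 and that of median widths 4.19 ± 0.0853 (SD, n = 2). With only peaks at a −log10 q of at least 5, which dropped more distal than promoter peaks, these ratios were 2.88 and 2.33.

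Among protein-coding genes, H3K4me2 at the promoter followed the CpG content of the sequence. Of 21851 genes, 14288 (65.4%) had a replicated peak within 1 kb of the 5' end. The share was 98.97% for the 10044 genes with a CpG-rich promoter and 36.8% for the 11807 others, an odds ratio of 166 (95% interval 136 to 202; Fisher's exact test, with a p below what the computer can hold as a number). Genes for olfactory and vomeronasal receptors, a family expressed in sensory neurons of the nose, carried a promoter peak in 3 of 1463 cases (0.205%). This family was chosen after the values were seen.

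The fixed lists of genes differed in how many of their promoters carried a peak. All 23 members of the facial signalling list did, among them the Hedgehog genes Shh, Ptch1 and Gli1 and the growth factor genes Bmp4 and Fgf8, as did all 16 of the surface epithelium list (Krt5, Krt14, Cdh1 and Irf6), all 14 of the sensory and general neuron list (Tubb3, Isl1 and Pou4f1) and all 14 housekeeping genes. The share among other genes was 65.4%, and the exact test gave adjusted p values of 0.000614, 0.0105, 0.0118 and 0.0118. In contrast, none of the 14 macrophage and leukocyte genes carried a promoter peak (Aif1, C1qa, C1qb and C1qc among them, genes for a macrophage protein and for complement), 2 of 14 hepatocyte genes did (Apoa1 and Trf, but not Alb or Afp, the serum albumin and fetoprotein genes), and 1 of 13 pluripotency and germ line genes did (Dazl, but not Ddx4, Dppa3 or Dppa4). Their adjusted p values in Fisher's exact test were 8.08e-06, 0.000714 and 0.000299. Without replicate 1 the hepatocyte count was 1, and without replicate 2 the leukocyte count was 1 and the germ line count 2, and all 3 lists stayed lower. Fgfr2 of the facial signalling list was counted by its outermost TSS, at 133123350 on chromosome 7, while its annotated span began at 130162451. The peak there may belong to another gene, which was not tested. Its covered length of 5103 bp and its distal peaks rest on the same 5' end. With a promoter window of 500 bp, 14 of 16 surface epithelium genes carried a peak and the list was no longer called (adjusted p = 0.127, exact test; range over all alternatives 0.000384 to 1). Among CpG-poor promoters only, an alternative chosen after the data were seen and covering all leukocyte and hepatocyte genes, 36.8% carried a peak. There the surface epithelium (11 of 11), facial signalling (7 of 7) and leukocyte (0 of 14) calls held, with adjusted p values of 0.000384, 0.0105 and 0.026 in the exact test (range over all alternatives 0.000438 to 1 for facial signalling and 4.06e-06 to 0.026 for leukocyte). The neuron (4 of 4), housekeeping (2 of 2), hepatocyte (2 of 14) and germ line (0 of 8) lists did not pass there, with adjusted p values of 0.106, 0.346, 0.324 and 0.139 in the exact test (ranges 0.0115 to 1 for the first 2, 0.000102 to 0.324 and 1.04e-06 to 0.139). The neuron, housekeeping and germ line counts were the most extreme possible for so few genes. Their loss of the call there therefore decides nothing. The tests were two-sided with Benjamini-Hochberg adjustment over 23 lists, and their units are genes and not animals, so here and below each p describes these lists in these libraries.

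The other 16 lists did not pass this test. It could not call the Dlx list higher even with all 6 members (raw p = 0.0993, exact test). Promoter peaks were found at 19 of 21 cranial mesenchyme transcription factors (not at Prrx2 or Tbx22; adjusted p = 0.055, exact test), all 6 Dlx genes, 7 of 12 anterior and 11 of 16 posterior Hox genes, 11 of 15 chondrocyte, 8 of 10 forebrain, 7 of 10 Schwann cell and glia and 8 of 13 endothelium genes. They were found at 6 of 13 osteoblast genes, 6 of 15 skeletal muscle genes, 5 of 12 cardiomyocyte genes, 4 of 10 tooth genes, 4 of 10 erythroid genes, 4 of 11 pancreas and gut genes, 3 of 10 suprabasal keratinocyte genes and 3 of 9 melanocyte genes. The osteoblast genes Runx2, Sp7, Col1a1, Col1a2, Satb2 and Alpl carried a peak, while the mineral matrix genes Bglap, Dmp1, Ibsp and Mepe did not. Without replicate 2, Dmp1 carried a peak (2.49-fold) and the osteoblast count was 7. Among tooth genes, Pitx2, Eda, Edar and Foxi3 carried a peak and the enamel and dentine matrix genes Ambn, Amelx, Dspp and Enam did not. Skeletal muscle genes with a peak included Pax7, Myf5, Des and Myod1, and those without included Ckm, Mef2c, Myh3 and Myh8. Of the melanocyte genes Kit, Mitf and Pmel carried a peak and Dct, Mlana, Oca2 and Slc45a2 did not. Of the endothelium genes Sox18, Esam, Cldn5 and Erg did and Cdh5, Egfl7, Emcn and Pecam1 did not, of the erythroid genes Tal1, Epor, Klf1 and Gypa did and Alas2, Ermap, Gata1 and Rhd did not, and of the cardiomyocyte genes Tnni3, Nkx2-5, Myl7 and Tbx5 did and Actc1, Myh6, Myh7 and Myl2 did not. Of the suprabasal keratinocyte genes Lor, Krtdap and Tgm1 carried a peak, and Flg, Ivl, Dsc1 and Dsg1a did not. Without replicate 1 the cranial mesenchyme list passed, with 20 of 21 members (adjusted p = 0.0106, exact test; range over all alternatives 0.00132 to 1). With 19 members it also passed at a −log10 q of at least 5 (adjusted p = 0.0336, exact test). The same held with peaks found in both libraries and with a 500 bp window (adjusted p = 0.0382 and 0.0263, exact test). It did not pass without replicate 2 or with the pooled list (adjusted p = 0.0548 and 0.0557, exact test). Nor did it at a −log10 q of at least 2 or within either CpG class. With a 2.5 kb window and with any TSS, 5 lists were called with more, 4 of them called before. The leukocyte, hepatocyte and suprabasal keratinocyte lists had no member with a CpG-rich promoter. Among the other 20 lists with CpG-rich promoters only, none was higher, since 98.97% of these promoters carried a peak. The 2 lower lists were pluripotency and germ line, with 1 of 5, and posterior Hox, with 7 of 10 (adjusted p = 1.04e-06 and 0.00119, exact test). The posterior Hox count depended on the library. In library 1 the CpG-rich members Hoxc12 and Hoxd10 had a promoter peak (3.17-fold and 5.62-fold), and the whole list had 13 of 16. Whether the call holds there was not tested.

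Cranial mesenchyme transcription factors were covered by H3K4me2 over long stretches around the 5' end. Their median covered length within 5 kb was 6563 bp, against a median of 2227 bp (95% range 1730 to 2867 bp) in random lists matched on CpG class. Six2 was covered over 10001 bp, the whole window, and the homeobox genes Msx1, Pax3 and Lhx8 over 9846, 8889 and 8739 bp. In the separate libraries these 4 genes had 9459 ± 318, 9555.5 ± 432, 8473 ± 540 and 7735 ± 491 bp (SD, n = 2). Six2 lies on chromosome 17 at 85684277 to 85688274 and Msx1 on chromosome 5 at 37820485 to 37824583. Posterior Hox genes, which pattern the trunk and limbs, had a median of 840.5 bp against 2164.5 bp (1583 to 2870 bp) in matched random lists. They were the only list called shorter, but a list whose random range reached 0 bp could not be called shorter. Hoxd13, on chromosome 2 at 74668310 to 74671599, had 2172 bp, while Hoxa9, Hoxc11 and Hoxd10 had 0 in the replicated list. Without replicate 2, Hoxd10 had 331 bp. Some posterior Hox genes have overlapping windows, such as Hoxd13 and Hoxd12 with 5' ends at 74668310 and 74675013 on chromosome 2. The random lists were not matched on this, so p values for this list may be too small. The difference of 5722.5 bp between cranial mesenchyme and posterior Hox genes had a permutation p of 1e-05, the smallest possible when the labels of their genes were permuted. These were the list with the longest median and the list called shorter, and this comparison was not matched on CpG class. Its p is therefore no evidence beyond the tests of each list.

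Facial signalling genes had a median of 5757 bp against 2268 bp, led by Ptch1 (10001 bp; 9739.5 ± 344 in the libraries), Pdgfra, a receptor gene of neural crest mesenchyme (9454 bp; 9059.5 ± 117), Fgfr1 (6949 bp) and Gli2 (6363 bp). Dlx genes, homeobox genes of the jaws, had 5173.5 bp against 2474.5 bp, with Dlx6, Dlx3, Dlx2 and Dlx5 between 5151 and 5469 bp. Chondrocyte genes had 3259 bp against 1090 bp, led by Sox9 on chromosome 11 at 112782224 to 112787760 (6620 bp; 6214 ± 43.8), Sox6 (6364 bp), Col2a1 (4570 bp) and Col11a1 (4054 bp). Surface epithelium genes had 3171.5 bp against 1275.5 bp, led by the splicing regulator genes Esrp2 and Esrp1 (5637 and 5288 bp), Irf6 (5243 bp) and Grhl2 (4696 bp). Osteoblast genes had 2563 bp against 437 bp, led by Col1a1 (8490 bp; 8179.5 ± 67.2), the main collagen gene of bone, and Satb2 (7639 bp; 7550 ± 158). Housekeeping genes had 4003.5 bp against 2486.5 bp, with Polr2a, Ubc, Tbp and Eef2 between 5066 and 5464 bp. In the permutation test against 100000 random lists, adjusted over 23 lists, p was 0.00023 for cranial mesenchyme and facial signalling, where the raw value of 2e-05 was the smallest possible, 0.00092 for chondrocyte, 0.00147 for surface epithelium and posterior Hox, 0.00199 for Dlx, 0.00263 for housekeeping and 0.0103 for osteoblast. The osteoblast call was lost without replicate 1 (1956 bp, adjusted p = 0.0802, permutation test) and also at a −log10 q of at least 5, within 2 or 20 kb and without CpG matching (permutation test, range over all alternatives 0.00477 to 1). The posterior Hox call was lost within 20 kb (2849.5 bp, adjusted p = 0.973) and against lists not matched on CpG class (adjusted p = 0.27, permutation tests; range over all alternatives 0.00107 to 0.973), and with a window of 2 kb only cranial mesenchyme and facial signalling were called higher. Forebrain genes were called within 20 kb (5462 bp, adjusted p = 0.0448, permutation test; range over all alternatives 0.0448 to 1). Covered length takes in peaks at promoters of neighbouring genes inside the window. Leaving these out was tried for the cranial mesenchyme list only.

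The remaining 15 lists were not called. Long stretches were nevertheless seen at single members: Pitx2 of the tooth list had 7146 bp, Pax7 of the skeletal muscle list 6344 bp, and Emx2 and Bcl11b of the forebrain list 8693 and 8165 bp. Among genes of blood and inner organs, Cd68, without a promoter peak, had 3652 bp of peaks elsewhere in the window, while Ptprc, Lyz2 and Csf1r had 0, as had Alb, Ins1, Gcg and Pou5f1. The medians were 0 bp for macrophage and leukocyte, hepatocyte, melanocyte, pluripotency and germ line, and pancreas and gut genes. Their random ranges began at 0 bp as well, so these lists could not be called shorter.

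**Figure D2:**
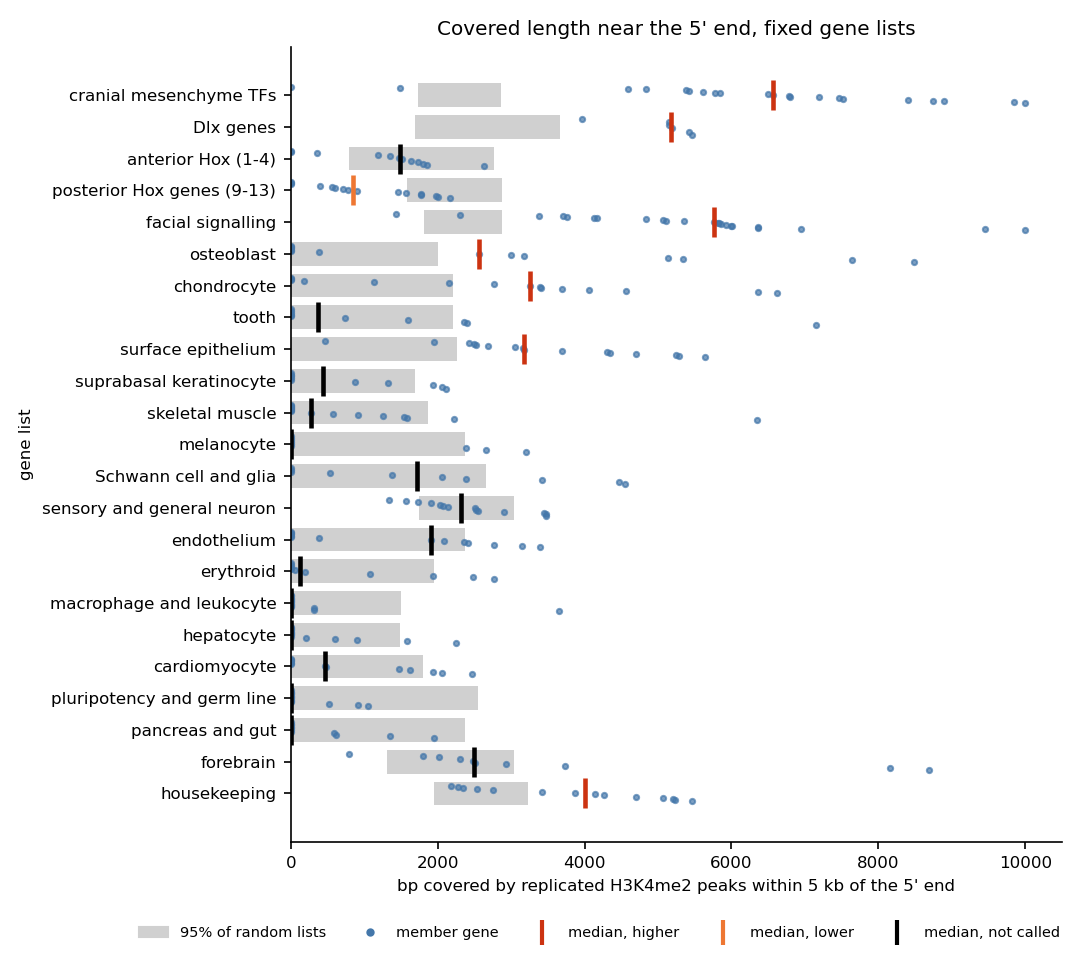
Base pairs covered by replicated peaks within 5 kb of the 5' end (x axis) for each fixed gene list (y axis). Dots are member genes, vertical marks the list's median (red called higher, orange called lower, black not called), and grey bars the central 95% of medians of random lists matched on CpG class. Cranial mesenchyme (6563 bp) and facial signalling (5757 bp) lie farthest to the right and posterior Hox (840.5 bp) lies left of its grey bar.

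Over all protein-coding genes, Ptch1 had the longest coverage within 10 kb of the 5' end in the replicated list, with 18059 bp, and was followed by the homeobox gene Meis2 (16907 bp), Bahcc1 (16796 bp), Ebf3 (16561 bp), Tbx3 (16050 bp), Pax3 (16042 bp), Nfib (15581 bp), the histone methyltransferase gene Setd1b (15357 bp), Skida1 (14899 bp) and Tnrc18 (14659 bp). In the separate libraries the means ranged from 14034 ± 188 bp for Tnrc18 to 15688.5 ± 1742 bp for Ptch1 (SD, n = 2). The order differed in library 2, where Ptch1 had 14457 bp and Pax3 15555 bp.

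Cranial mesenchyme transcription factors also had many distal peaks nearby. They had a mean of 6.81 replicated peaks per gene that were over 1 kb from every TSS and nearest to their 5' end, against 1.76 (0.810 to 3.14) in random lists matched on the length of the surrounding territory. Twist2 had 16 such peaks and Alx1 14, named after their values were seen. Without replicate 2 Twist2 had 27, and without replicate 1 Alx1 had 22. Forebrain genes had 5.50 against 1.73, with 16 near Bcl11b, or 28 without replicate 1, and 10 near Emx2. Dlx genes had 3.83 against 0.808, facial signalling genes 3.61 against 1.72, chondrocyte genes 3.6 against 1.41, surface epithelium genes 2.31 against 0.767 and housekeeping genes 1.57 against 0.492. Adjusted p values in the permutation test were 0.00046 for cranial mesenchyme, 0.0154 for Dlx, 0.0187 for forebrain, 0.033 for surface epithelium, 0.0358 for housekeeping, 0.0384 for facial signalling and 0.0448 for chondrocyte. No list was lower, and the raw p of 2e-05 for cranial mesenchyme was the smallest that the permutation test can give. These random lists were not matched on CpG class. Genes with a CpG-rich promoter had a mean of 1.09 distal peaks, against 0.564 for the others. How much of the calls comes from this was not tested. Osteoblast genes (2.62 against 1.14, adjusted p = 0.107) and anterior Hox genes (1.00 against 0.351, adjusted p = 0.102) did not pass the permutation test, and neither did the other 14 lists. Without replicate 2, the chondrocyte call was lost (4.33 peaks per gene, adjusted p = 0.111, range over all alternatives 0.00368 to 0.21) and osteoblast genes were called (4.54, adjusted p = 0.0396, range 0.0266 to 0.579, permutation tests). The lists of single libraries hold more distal peaks: without replicate 1 the means rose to 10.8 for cranial mesenchyme, 5.91 for facial signalling and 3.75 for surface epithelium, and without replicate 2 to 5.57 for facial signalling and 3.69 for surface epithelium, all still called. Cranial mesenchyme and forebrain were called under each alternative run, and were the only ones called with peaks over 5 kb from every TSS. With the pooled list the Dlx, chondrocyte and housekeeping calls were lost, and without territory matching the Dlx, surface epithelium and housekeeping calls were lost. With peaks at a −log10 q of at least 5, or found in both libraries, the facial signalling and chondrocyte calls were lost. The chondrocyte call was also lost at a −log10 q of at least 2 and within 100 kb of the 5' end, where osteoblast genes were called (adjusted p = 0.0266, permutation test; range over all alternatives 0.0266 to 0.579).

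**Figure D3:**
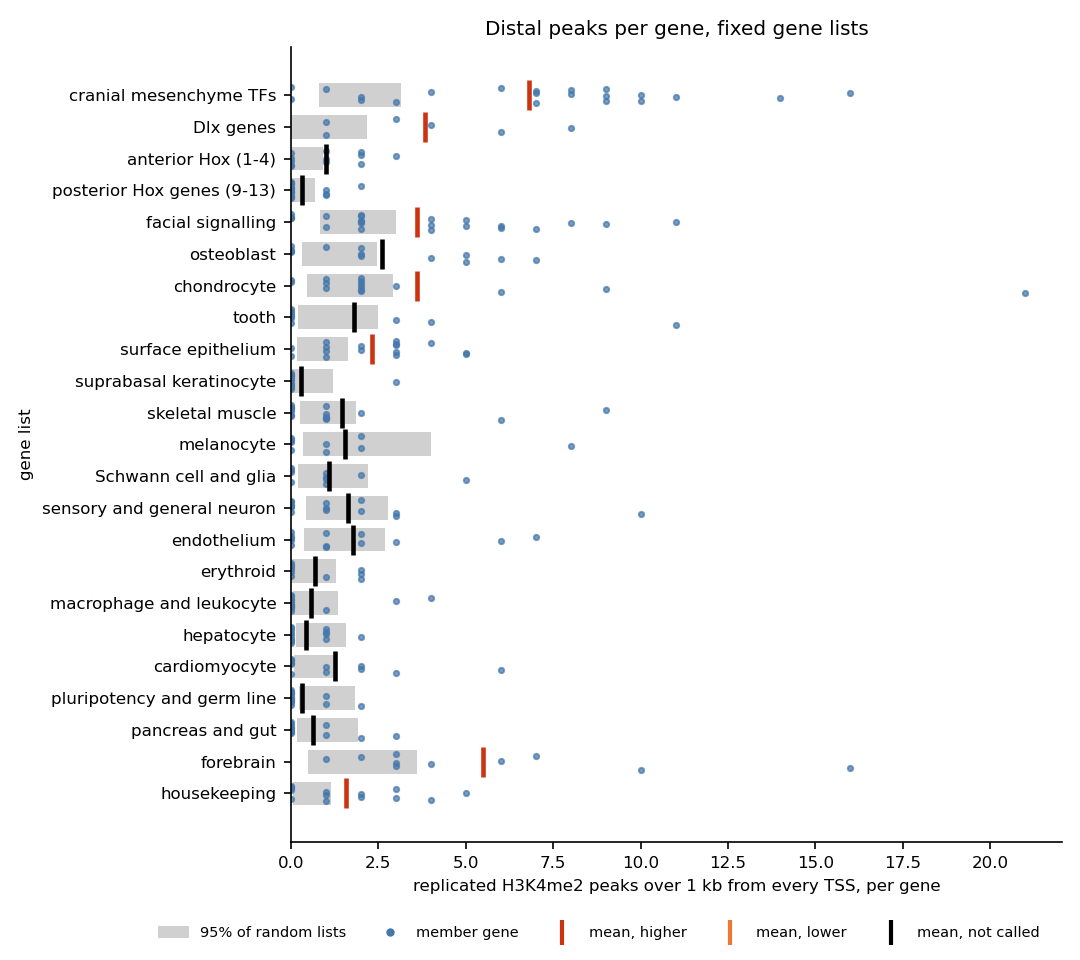
Replicated peaks over 1 kb from every TSS per gene (x axis) for each fixed gene list (y axis). Dots are member genes, vertical marks the list's mean (red called higher, black not called), and grey bars the central 95% of means of random lists matched on territory length. The mean was 6.81 for cranial mesenchyme and 5.50 for forebrain, both right of their grey bars.

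Adgrl2, an adhesion receptor gene, had the most distal peaks of all protein-coding genes in the replicated list, 36, followed by Zfp608 with 34, Zfhx3 with 31, Trps1, a regulator of cartilage and hair, with 28, and Med13l, Tcf4 and Pmfbp1 with 25 each. Nfib and Smad7 had 22 each, and Sox9, a regulator of cartilage, had 21, as had Tbx3 and Tenm3. In the separate libraries Adgrl2 had 45.5 ± 2.12, fewer than Zfp608 with 47 ± 2.83, and Sox9 had 22.5 ± 0.707 (SD, n = 2), while Nfib had 38 without replicate 1 and 35 without replicate 2, Tcf4 had 43 without replicate 2 and Tenm3 34 without replicate 1. Of all protein-coding genes, 14307 had no distal peak, and the mean was 0.806 per gene. The ranking was not adjusted for territory length. Pmfbp1 had no promoter peak and 0 bp covered within 5 kb. The end of Zfhx3 at 108961630 on chromosome 8 lies nearer to the 5' end of Pmfbp1 (109494027) than to that of Zfhx3 (107942644). Peaks inside Zfhx3 may therefore have been counted for Pmfbp1.

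Chromosome X had fewer peaks per megabase than the autosomes. It carried 6.48 peaks per megabase in library 1 and 6.77 in library 2, against means over the 19 autosomes of 19.1 ± 4.01 and 19.2 ± 3.97 (SD over autosomes), whose lowest values were 13.02 and 13.29. The ratio of X to the autosomal mean was 0.345 ± 0.00924 (SD, n = 2). Covered length was 6.89 kb per megabase on X in library 1 and 6.80 in library 2, against 19.2 and 18.9 on the autosomes. CpG-rich promoters were also sparser on X, at 1.41 per megabase against a mean of 4.16. Near a TSS lay 739 of the 1060 X peaks in library 1 and 770 of 1106 in library 2, against 43.6% and 44.7% of all peaks. In the pooled list, 23.5% of X peaks were under 4-fold over background, against 48.1% on the autosomes. Chromosome Y had 8 peaks in each library. With peaks at a −log10 q of at least 5 the X ratio was 0.448.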

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

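This check of sequences outside the chromosomes analysed was chosen after the data were seen. The replicated list held 14 peaks off chromosomes 1 to 19, X and Y, on mitochondrial DNA and on sequences of the assembly outside the chromosome sequences. They were counted in the overlap of the libraries but in no comparison with genes. The highest fold over background among them was 12.4.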

How the results depend on the processing

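The alternatives with only replicated peaks found in both libraries and with CpG-poor promoters only were chosen after the data were seen, and the others before. The share of library 1 and library 2 peaks found in the other library was 77.5% and 79.1% with 1 bp of overlap, 63.3% and 62.8% with 50% of both peaks (rho 0.938), 77.1% and 79.5% at a −log10 q of at least 2, and 88.3% and 93.1% at 5 or more (rho 0.912). Leaving out a library leaves no overlap to compute. The ratio of median folds of replicated to other pooled peaks was 3.62 at a −log10 q of at least 2. The promoter to distal ratios of fold and width were 4.74 and 4.45 with a 500 bp window, 3.78 and 3.39 with 2.5 kb, 4.18 and 3.74 at a −log10 q of at least 2, and 2.88 and 2.33 at 5. The X ratio was 0.372 and 0.448 at these values. Lists with fewer promoter peaks numbered 6 with a 500 bp window, of which 3 were called before. There 3 of the 4 lists called with more kept that call, and cranial mesenchyme was newly called (19 of 21, adjusted p = 0.0263, exact test). Lists with more numbered 0 among CpG-rich promoters. There posterior Hox genes turned from 11 of 16, near the share of other genes, to 7 of 10, below it. Without replicate 2 the whole posterior Hox list had 13 of 16, with peaks at the CpG-rich Hoxc12 and Hoxd10. Whether the turn holds in that library was not tested. Among CpG-poor promoters, lists with more promoter peaks numbered 2 and lists with fewer 1, all called before. Lists with longer coverage numbered 2 within 2 kb. Lists with shorter coverage numbered 0 within 20 kb, where posterior Hox genes turned to the longer side (2849.5 bp), and 0 without CpG matching. Lists with more distal peaks numbered 4 with the pooled list, 4 without territory matching and 2 over 5 kb from every TSS, all among the 7 called before. Without 1 library, the excess near TSSs was 6.64-fold to 6.86-fold, against 4.42-fold to 9.05-fold over all alternatives, and lists with longer coverage numbered 6 to 7. The cause was not tested in any of these cases. For single lists, 613 values kept their side of the threshold, 37 lost the call, 12 gained it and 2 reversed. With only replicated peaks found in both libraries, lists with longer coverage numbered 7 and lists with more distal peaks 5. Peaks without a partner in the other library had a median summit pileup of 12 fragments in library 1 and 11 in library 2. How depth limits their detection was not tested.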

Other observations

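The test of promoter copies was chosen after the data were seen, and the other tests in this part before their results were seen. Of 10044 CpG-rich promoters, 103 had no replicated peak, and 93 of these had none in either library. The 103 included the germ line and meiosis genes Sycp1, Sycp3, Ddx4 and Mael of the fixed lists, beside Sycp2, Hormad1, Spo11 and Mov10l1. They also included the posterior Hox genes Hoxc11, Hoxc12 and Hoxd10, of which Hoxc12 and Hoxd10 had a promoter peak in library 1. Genes outside the lists were picked after their values were seen. The promoter sequence of 51 of the 103 (49.5%) was found at 2 or more places on the chromosomes (98% identity over 90% of 500 bp on either side of the 5' end), against 27 of 9941 (0.272%) with a peak (Fisher's exact test, p = 6.51e-88 across genes). Tmem254a, Plac9a and Srp54b were among them, and the meiosis and Hox genes named here were each found at 1 place. Copies of the same family, such as Tmem254a, Tmem254b and Tmem254c, were counted as separate genes, so the p of this test overstates the evidence.

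Cranial mesenchyme transcription factors had long covered stretches around their 5' ends. CpG-rich sequence does not account for it alone: against lists matched on the number of CpGs within 5 kb, the median of 6563 bp stood against 3500 bp (2768 to 4401 bp; permutation p = 2e-05, the smallest possible). Nor do neighbouring promoters, since 5465 bp against 1582 bp remained after peak length within 1 kb of other genes' TSSs was left out (permutation p = 2e-05). Matching on the number of TSSs left 6563 bp against 1919 bp (permutation p = 2e-05). The median promoter fold of the members was 19.7, against 22.6 over all genes with a promoter peak. With 1 tissue, no biological explanation was tested.

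Posterior Hox genes had shorter covered stretches than lists matched on CpG class. A shortage of CpGs is argued against, since the median of 840.5 bp stood against 3622 bp (2872 to 4610.5 bp) in lists matched on CpG number (permutation p = 2e-05). Members with overlapping windows were counted as separate genes, so this p may be too small. Weak enrichment that leaves peak edges under the threshold stays open. Only the 11 members with a promoter peak could be matched on promoter fold. Their median promoter fold was 7.96, against 22.6 over all genes with a promoter peak, and their median covered length was 1572 bp against 1604 bp (877 to 2495 bp; permutation p = 0.92). This decides nothing, because the other 5 members, without a promoter peak, were left out and the height and length matched and tested belong to the same peaks. With 1 tissue, no biological explanation was tested.

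Chromosome X had fewer peaks per megabase than the autosomes. Peaks at CpG-rich promoters numbered 324 on X and 10888 on the autosomes in library 1, and 337 and 11506 in library 2. Over these peaks the median summit pileup on X was 41 against 87 fragments in library 1, a ratio of 0.471 (95% bootstrap interval 0.455 to 0.506). In library 2 it was 34 against 72, a ratio of 0.472 (0.438 to 0.5). The mean ratio was 0.472, while single autosomes ranged from 0.920 to 1.08 in library 1. The units were peaks, so a promoter with several peaks counted more than once. In pools of equal sexes a lower X copy number alone would give 0.75, which both intervals exclude for these peaks. If X promoters were split into more peaks, lower pieces would reduce the ratio, and this was not tested. A silenced X in females on top of it would give 0.5, and the values may come from that, although the sex shares of the pools are not known. Sparser genes on X may lower the peak number too: CpG-rich promoters lay at 1.41 per megabase on X, against a lowest autosomal value of 2.89. How much of the lower peak number comes from this and how much from a lower pileup cannot be told apart here. The planned test decided nothing. X had 3.28 peaks near a TSS per CpG-rich promoter, above the autosomal range of 1.80 to 2.34, a case the test had not provided for. That count takes in peaks at any TSS of any gene, so it does not measure CpG-rich promoters alone.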
